A study of Homo sapiens with 18 samples.

How the data were processed

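Gene expression was measured in LNCaP cells, an established androgen-responsive line derived from a lymph node metastasis of a prostate carcinoma. Per the labels, the cells were kept in medium with 5% hormone-depleted serum and were treated for 16 h. The treatments were the solvent DMSO (vehicle), 100 nM dihydrotestosterone (DHT, a natural androgen), enzalutamide (an antiandrogen) at 1 or 10 µM, and 100 nM DHT together with enzalutamide at 1 or 10 µM. Each of the 6 groups had 3 arrays, 18 in all, and groups and replicate numbers were taken from the labels. No label states that the replicates came from separate cultures, so the p-values measure the spread between these samples, which may be technical.

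Total RNA was turned into biotin-labelled cRNA and hybridised to single-colour oligonucleotide arrays, per the labels. The array model is not given in the sources used here. The submitters' processing notes name MAS5 without a version, and other steps are not given in the sources used here. The deposited array values were on a log2 scale, per the file headers and the values themselves. After undoing the log, the 2% trimmed mean signal lay between 500.0 and 500.1 on every array, so the arrays had been scaled to a common level before deposit. The array medians ran from 6.87 to 7.18 on the log2 scale. A second deposited table, which pairs the same values with log ratios between groups, held identical array values (largest difference 0). The authors' deposited table of comparisons also gives p-values per probe set and marks the probe sets that passed in each pair of groups, per the file headers. Its 3717 marked probe sets were those whose overall p-value passed a Benjamini-Hochberg adjustment at 0.05, the highest being 0.0034. Log ratios in the authors' deposited table were used only for the direction of its marked probe sets.

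The arrays held 54675 probe sets, of which 62 were controls and were left out. In the deposited annotation 10476 probe sets had no usable gene symbol, 573 had several, and 43564 had a single symbol. No gene was named from a probe set with several symbols. Symbols were brought up to date with a RefSeq gene table of assembly GRCh38.p14, used for names only. In that step 38279 probe sets were named through a RefSeq accession, 1224 matched a current symbol, 1080 matched an older synonym, and 2981 kept the name in the annotation. This gave 19174 genes. No genome came with the data, so no positions are given.

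The values were used as deposited, with no further normalization, since they were already on a log2 scale. Probe sets with a mean log2 signal under 6.98, the median of all, were left out, and each gene was represented by its probe set of highest mean. This left 12751 genes. limma 3.58.1 in R 4.3.3 fitted the 6 group means to all 18 arrays with 12 residual degrees of freedom, and eBayes with an intensity trend gave two-sided p-values. P-values were adjusted by Benjamini-Hochberg over the genes of each comparison, and a gene was called at an adjusted p under 0.05. The same model gave the interaction of DHT with each dose, the effect of DHT beside the drug minus its effect without it. Changes are log2 differences between group means, with the standard error of the fit after the sign ±, and n = 3 arrays per group. The number of arrays limits the precision. A gene passed the brightness limit by its mean over all arrays, so single group means can lie below it, and the size of a change from or to such a level is uncertain. Tables were computed with Python 3.11.15, numpy 2.4.6, pandas 2.3.3 and scipy 1.17.1, and plots were drawn with matplotlib 3.10.9.

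The share of the DHT response kept beside enzalutamide was the least-squares slope through 0, over the genes called for DHT, of the DHT effect beside the drug (DHT with enzalutamide minus enzalutamide alone) on the DHT effect without it. Its error is a jackknife over arrays. A second value took the genes and the DHT effect from different arrays, since genes chosen for a large effect have overstated effects.

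Gene lists were tested with camera in limma at a preset inter-gene correlation of 0.01, two-sided, with Benjamini-Hochberg adjustment over the lists of a comparison, and again with an estimated correlation. The 23 lists were androgen-induced genes, androgen-repressed genes, cholesterol synthesis, fatty acid synthesis, polyamine metabolism, glycolysis, the unfolded protein response, ATF4 and amino acid genes, DNA replication, mitosis, p53 and apoptosis genes, immediate early genes, PXR drug metabolism, AHR drug metabolism, NRF2 oxidative response, neuroendocrine markers, luminal markers, basal epithelial markers, fibroblast markers, leukocyte markers, glucocorticoid response, ribosome biogenesis and housekeeping genes. Lists with fewer than 4 tested members (basal epithelial and leukocyte markers, 3 each) were described by their members. Counts of called members are given over all genes tested and, where stated, also adjusted over the list alone. Some genes are on more than a single list: SGK1, FKBP5 and ZBTB16 are on the androgen-induced and glucocorticoid lists, and ACSL3 on the androgen-induced and fatty acid lists.

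Genes were named by a rule. For each comparison it took the 10 largest positive and the 10 largest negative log2 changes among called genes whose groups did not overlap, so that all 3 arrays of a group lay beyond all 3 of the other. For interactions the adjusted p alone decided. Members of the lists could also be named, and KLK3, TMPRSS2 and FKBP5 are given in all groups. Values of some genes that the rule or the lists include are not reported here, though such genes count in the totals. The groups, comparisons, tests, filter, lists, naming rule and most other settings tried were chosen before the data were examined.

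The fit was tested on simulated data for DHT against vehicle, with 200 of 12751 genes changed in each of 10 runs. It called 36.9% of genes changed by 0.5 on the log2 scale, 83.0% of those changed by 1 and 98.2% of those changed by 2, and 5.6% of its calls were false. A kept share set to 30.0% came back as 28.3%. Interactions were called for 31.4% of genes with a change of 1 and 77.8% with a change of 2. A simulated comparison without change gave 0 calls with limma. The simulated noise was independent between genes and had the same spread on every array. These rates therefore do not cover arrays of uneven quality or noise that genes share.

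For overlaps between comparisons that share arrays, 50 simulations of unchanged groups gave the covariance that shared arrays of equal spread produce alone. Such groups gave no calls, so the simulated overlap was 0 throughout and is no measure of what shared arrays add to a count. Noise in these simulations was again independent between genes, with the same spread on every array. The covariance from real arrays of uneven quality may therefore be larger or smaller than the simulated value. The vehicle group of 3 arrays cannot be split into parts of at least 2, so part of any excess may come from the shared arrays.

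The other settings chosen then were leaving out each array in turn, centring each array on its median, quantile normalization, array weights, the replicate number as a block, fitting the compared groups only, testing all probe sets, eBayes without a trend, no filter, and a stricter filter at a mean log2 of 8.46 that kept 30.0% of probe sets. Chosen after seeing the data were a fit without the arrays of high ACTB 3′ to 5′ ratio, that ratio as a covariate, and log2 of the signal plus 16.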

Results

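Transcript levels were measured in LNCaP prostate carcinoma cells after 16 h with vehicle, the androgen DHT, the antiandrogen enzalutamide at 1 or 10 µM, or DHT together with either dose. Each of the 6 groups had 3 arrays, and 12751 genes were bright enough to be tested. Across all probe sets, which are not independent replicates, the 18 pairs of arrays within a group correlated with r between 0.924 and 0.962, and the 135 pairs from different groups with r between 0.912 and 0.958. On 2 arrays, replicate 2 of DHT and replicate 2 of enzalutamide 1 µM, the ACTB probe set at the 3′ end was 4.50 and 6.04 times as bright as the probe set at the 5′ end. This ratio, a common sign of RNA integrity, lay between 1.42 and 1.80 on the other arrays. The same ratio of GAPDH was 1.21 and 1.12 on these arrays. The total counts of called genes below are therefore also given without them. Counts of list members are from all arrays unless stated, and some of them change without these 2.

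**Figure D1:**
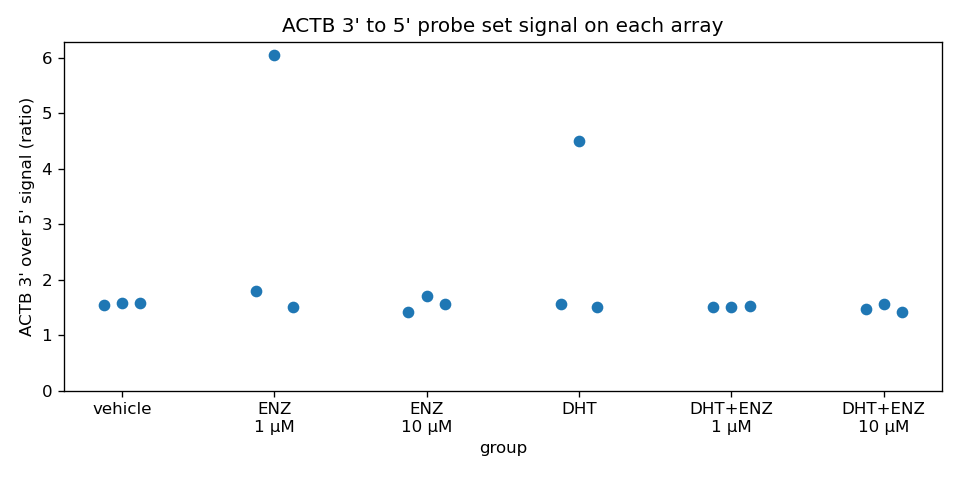
The ratio of the ACTB 3′ signal to the ACTB 5′ signal (vertical axis, no unit) is plotted for each array, 3 points per group, by group (horizontal axis; ENZ, enzalutamide). Replicate 2 of enzalutamide 1 µM at 6.04 and replicate 2 of DHT at 4.50 lie above all other arrays.

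Levels in this paragraph are given as mean ± SD of 3 arrays. KLK3, which encodes prostate-specific antigen, stood at 10.15 ± 0.20 with vehicle, 10.69 ± 0.74 and 11.37 ± 0.21 with 1 and 10 µM enzalutamide, 14.19 ± 0.10 with DHT, and 14.33 ± 0.14 and 13.97 ± 0.16 with DHT and either dose. TMPRSS2, a serine protease gene, went from 8.48 ± 0.17 with vehicle to 13.10 ± 0.11 with DHT and stood at 12.03 ± 0.28 and 10.78 ± 0.32 when 1 or 10 µM enzalutamide was added. It was 8.11 ± 0.43 and 8.29 ± 0.60 with the drug alone. FKBP5, a co-chaperone of steroid receptors, went from 9.47 ± 0.08 to 13.79 ± 0.04 with DHT and stood at 11.71 ± 0.51 and 10.22 ± 0.05 when 1 or 10 µM was added. With the drug alone it was 9.65 ± 0.05 and 9.64 ± 0.13.

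**Figure D2:**
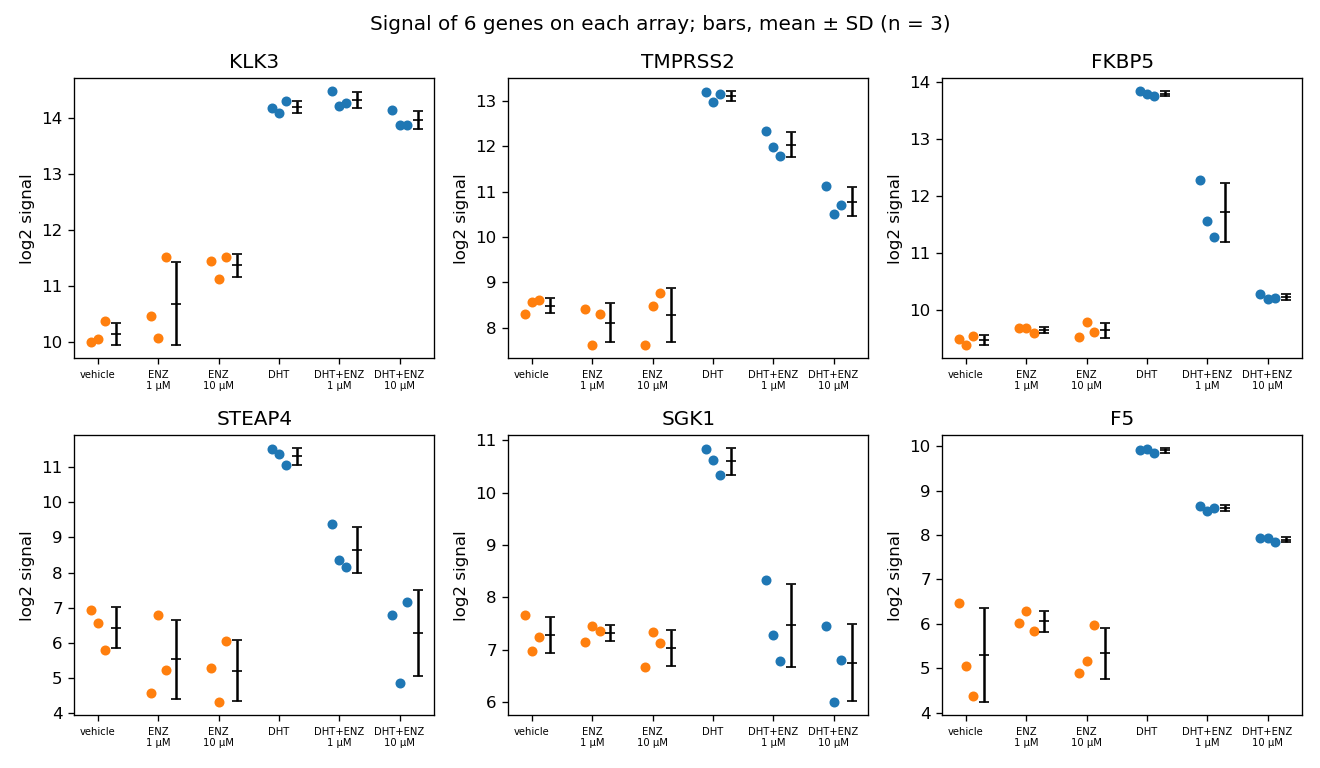
The log2 signal (vertical axes) of KLK3, TMPRSS2, FKBP5, STEAP4, SGK1 and F5 is plotted for each array by group (horizontal axes), blue for groups with DHT and orange for groups without, with bars for the mean and SD of 3 arrays. FKBP5 stood at 13.79 with DHT and 10.22 with DHT and 10 µM enzalutamide (ENZ), whereas KLK3 stood at 14.19 and 13.97.

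The comparison of DHT with vehicle shows what the androgen changed. KLK2, a kallikrein protease of the prostate, rose by 8.27 ± 0.39 on the log2 scale (adjusted p = 2.54e-11, n = 3 per group), from a vehicle level of 5.45 that lay below the brightness limit of 6.98, and its other probe sets gave 5.20, 5.94 and 0.12, so the size of the rise is uncertain. STEAP4, a metalloreductase, rose by 4.88 ± 0.58 (adjusted p = 5.92e-06), TMPRSS2 by 4.62 ± 0.25, coagulation factor F5 by 4.60 ± 0.37, FKBP5 by 4.32 ± 0.16 (adjusted p = 2.03e-12) and KLK3 by 4.05 ± 0.23 (adjusted p = 2.6e-10), or 16.5-fold. The other probe sets of KLK3 gave 4.86 and 1.58, so the size of its rise is uncertain as well. NNMT, a nicotinamide methyltransferase, rose by 4.21 ± 0.41, PMEPA1 by 3.51 ± 0.15, HPGD, which degrades prostaglandins, by 3.46 ± 0.22, and the kinase SGK1 by 3.32 ± 0.35. Falls were found for LRRC31 at -3.27 ± 0.45, the Golgi mannosidase MAN1A1 at -3.18 ± 0.18, SPTLC3, a subunit of serine palmitoyltransferase, at -3.15 ± 0.24, MID1 at -2.97 ± 0.41 and the adhesion molecule AMIGO2 at -2.92 ± 0.18. STXBP5L (-2.71 ± 0.13), SI, sucrase-isomaltase (-2.61 ± 0.18), the kappa opioid receptor OPRK1 (-2.60 ± 0.45), CD200 (-2.52 ± 0.34) and LRRN1 (-2.45 ± 0.11) also fell, with adjusted p-values of 0.000359 or less. STEAP4, F5, NNMT and HPGD with vehicle, and LRRC31, MAN1A1, SPTLC3, MID1, SI, OPRK1 and CD200 with DHT, also lay below the limit, so the sizes of their changes are uncertain too.

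Of the 28 tested androgen-induced genes 27 rose with DHT, also when adjusted over the list alone, with a median change of 2.25 (camera adjusted p = 6.07e-52). Only IGF1R, at 0.01, was not called. The transporter gene ABCC4 rose by 2.71 ± 0.12 and SLC45A3 by 2.50 ± 0.11. Of 11 androgen-repressed genes 9 fell (also 9 adjusted over the list alone, median -1.10, adjusted p = 3.52e-11), among them the steroid-conjugating enzymes UGT2B15 (-1.49 ± 0.09) and UGT2B17 (-1.60 ± 0.14) and CAMK2N1 (-1.46 ± 0.13). Cholesterol synthesis genes rose together: 18 of 23 were higher and HSD17B7 was lower (-0.33 ± 0.08), 18 and 1 when adjusted over the list alone, with a median of 0.70 (adjusted p = 9.45e-16). INSIG1, which controls sterol synthesis, rose by 1.47 ± 0.13, FDFT1 by 0.79 ± 0.12, ACAT2 by 0.78 ± 0.08 and squalene epoxidase, SQLE, by 0.74 ± 0.09. Of 17 fatty acid synthesis genes 10 rose (10 adjusted over the list alone, median 0.37, adjusted p = 1.03e-06), including the elongase ELOVL7 by 2.48 ± 0.12, ACSL3 by 1.48 ± 0.10 and FASN by 0.73 ± 0.23. Polyamine genes rose in 5 of 9 cases (5 adjusted over the list alone, median 0.50, adjusted p = 0.000457), with spermine synthase SMS at 1.44 ± 0.10 and ornithine decarboxylase ODC1 at 0.81 ± 0.09.

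Glucocorticoid response genes rose in 6 of 10 cases and fell in 2, TSC22D3 (-0.46 ± 0.12) and DUSP1 (-0.49 ± 0.16), and 6 rose and 3 fell when adjusted over the list alone (median 0.71, adjusted p = 6.71e-05). Besides genes shared with the androgen-induced list, ERRFI1 rose by 1.98 ± 0.10 and CEBPD by 0.89 ± 0.10. Of 19 genes of the unfolded protein response 8 rose (8 adjusted over the list alone, median 0.24, adjusted p = 0.000144), with DNAJB9 at 1.51 ± 0.10 and the sensor ERN1 at 0.98 ± 0.17. That list did not pass with an estimated correlation (adjusted p = 0.0772 with an estimated correlation), whereas the lists named before it did. Ribosome biogenesis genes NOP16 (0.82 ± 0.16), NOP58 and NOP56 rose out of 16, also 3 adjusted over the list alone (median 0.24, adjusted p = 0.000995). Among 5 tested fibroblast markers, FN1 (-1.16 ± 0.13) and COL1A1 (-0.78 ± 0.13) fell, 2 also adjusted over the list alone (median -0.36, adjusted p = 0.00596). Both of these lists also passed with an estimated correlation (adjusted p = 0.0233 and adjusted p = 0.0351 with an estimated correlation).

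The remaining lists did not pass for DHT. ATF4 and amino acid genes had 1 of 16 higher and 5 lower (1 and 7 adjusted over the list alone, adjusted p = 0.0541), with CHAC1 at -1.33 ± 0.29. DNA replication genes had 4 of 21 higher and 1 lower (5 and 1 adjusted over the list alone, adjusted p = 0.0541), and here cyclin E2, CCNE2, fell by 1.81 ± 0.12 while FEN1 rose by 0.84 ± 0.18. Mitosis genes had CCNB1 and CCNB2 higher out of 24 (0 adjusted over the list alone, limma, adjusted p = 0.0541), and p53 and apoptosis genes had 3 of 13 lower (3 adjusted over the list alone, adjusted p = 0.0592), with the death receptor FAS at -1.07 ± 0.17. Without the arrays of high ACTB ratio limma called 0 mitosis genes. Glycolysis genes had 1 of 17 higher, HK2 at 1.06 ± 0.15 (1 adjusted over the list alone, adjusted p = 0.225). The NRF2 list had GCLC lower (-0.72 ± 0.14) out of 8 (adjusted p = 0.287), and the immediate early list had MYC (0.49 ± 0.12) higher and JUN (-0.41 ± 0.07) and DUSP1 lower out of 8 (adjusted p = 0.287). Housekeeping genes had 3 of 15 higher, with a median of -0.05 but a mean of 0.05 (adjusted p = 0.351). Luminal markers had 4 of 12 higher and 3 lower, with a median of -0.16 but a mean of 0.24 (adjusted p = 0.694): keratins KRT8 (1.04 ± 0.27) and KRT18 (0.80 ± 0.12) rose while prostatic acid phosphatase, ACP3, fell by 1.26 ± 0.11. The AHR list (TIPARP 0.96 ± 0.13, adjusted p = 0.706, median -0.05, mean 0.16), the PXR list (1 of 4 lower, adjusted p = 0.784, lower by camera with a median of 0.01) and neuroendocrine markers (TUBB3 0.44 ± 0.11, ENO2 -0.78 ± 0.12, adjusted p = 0.849, median 0.09, mean -0.01) did not pass. Of 3 basal epithelial markers DST was lower (-0.56 ± 0.17), and none of 3 leukocyte markers was called.

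With DHT 2056 of the 12751 genes were called (16.1%), 995 higher and 1061 lower, and 358 changed at least 2-fold. In 32.4% of all genes the groups of 3 arrays did not overlap, where chance gives 10%. The same share was 25.6% for 10 µM enzalutamide against vehicle, where 104 genes (0.8%) were called. A share above 10% is therefore no measure of how many genes DHT changed. Without the arrays of high ACTB ratio the count was 2124, 916 higher and 1208 lower, and 1727 genes were shared, all in the same direction. Of the called genes 48.4% were higher, against 64.8% of 1420 after each array was centred on its median, a step that adds 0.10 to every DHT change. The authors' deposited table marks 2539 probe sets for vehicle against DHT, 1340 of them higher and 1199 lower with vehicle.

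**Figure D3:**
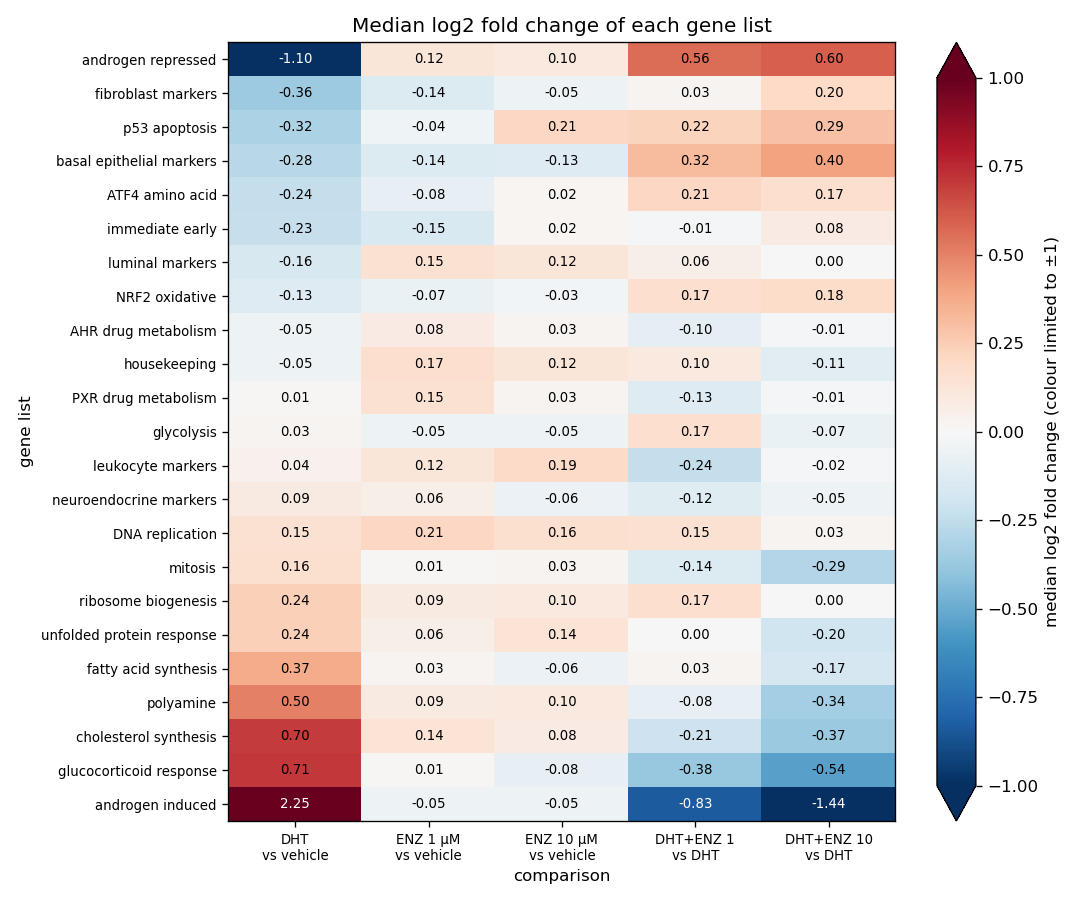
The median log2 fold change of each gene list (vertical axis) is given as colour and number for 5 comparisons (horizontal axis), with the colour limited to changes of 1 either way. The androgen-induced list stands at 2.25 for DHT against vehicle and at -1.44 when 10 µM enzalutamide (ENZ) was added to DHT.

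Enzalutamide at 1 µM without DHT asks what the antagonist does alone. FBLN1, a matrix protein gene, rose by 1.92 ± 0.51 (adjusted p = 0.0319), the synaptotagmin SYT4 by 1.28 ± 0.12 (adjusted p = 1.78e-05), IGFBP4 by 1.26 ± 0.33, the defensin DEFB132 by 1.20 ± 0.23, SKI by 1.15 ± 0.34, MYL3 by 1.12 ± 0.27 and PRR16 by 1.08 ± 0.18, as did LOC284017, SSC4D and TSPY26P by 1.45, 1.38 and 1.34. PYCR3, an enzyme of proline synthesis, fell by 2.45 ± 0.42 (adjusted p = 0.00502), and neurogranin, NRGN, fell by 2.25 ± 0.31 (adjusted p = 0.00211). KLF16 (-2.36 ± 0.57), the kinesin KIF1A (-1.97 ± 0.45), UNC119 (-1.90 ± 0.41), CIAO3 (-1.68), DHX38 (-1.66), ZBTB7B (-1.65), COL6A2, a collagen VI chain (-1.64), and RAB4B (-1.59) also fell. In the same group replicate 2 had the ACTB ratio of 6.04, and FBLN1, SSC4D, TSPY26P, IGFBP4, KLF16 and ZBTB7B were no longer called without the arrays of high ratio. FBLN1, LOC284017, SSC4D, TSPY26P and IGFBP4 with vehicle, and PYCR3 (4.62), NRGN (5.33), KLF16, UNC119, CIAO3, DHX38 and COL6A2 with 1 µM, lay below the brightness limit, so the sizes of their changes are uncertain.

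No gene list passed at 1 µM. DNA replication came closest, with RRM2 (0.68 ± 0.15), UHRF1 (0.63 ± 0.18) and TYMS (0.41 ± 0.12) higher out of 21, 6 adjusted over the list alone (adjusted p = 0.0729), and without the arrays of high ACTB ratio 1 member was called. Of the androgen-induced genes only PLPP1 rose (0.40 ± 0.09), with a list median of -0.05 (adjusted p = 0.939), and of the androgen-repressed genes BCHE rose by 0.66 ± 0.15. Among cholesterol synthesis genes 2 were higher, HSD17B7 (0.32 ± 0.08) among them, and 1 was lower. Fatty acid synthesis genes had 3 higher, ELOVL6, FADS1 and HSD17B12, and 2 lower, FASN (-0.83 ± 0.23) and TECR. Without the arrays of high ACTB ratio limma called 2 of this list higher and 0 lower, so FASN and TECR were no longer called. The pioneer factor FOXA1 fell by 0.60 ± 0.09 (adjusted p = 0.00276) and the transferrin receptor TFRC rose by 0.83 ± 0.10 (adjusted p = 0.000428). TXNRD1, a thioredoxin reductase, fell by 0.33 ± 0.09. No member of the AHR, ATF4, fibroblast, glucocorticoid, glycolysis, basal or leukocyte lists was called by limma.

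In total 872 genes were called at 1 µM, 286 higher and 586 lower. Without the arrays of high ACTB ratio 425 were called, 104 higher and 321 lower, and 369 were shared. Higher genes made up 32.8% of the calls, and 13.4% of 329 after centring. The count was 123, 221 and 383 without vehicle replicate 1, 2 or 3, 216 without enzalutamide 1 µM replicate 2, and 1780 without its replicate 3. The authors' deposited table marks 203 probe sets for this pair of groups.

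At 10 µM enzalutamide alone, 3 androgen-induced genes rose, among them KLK2 by 1.76 ± 0.39 (adjusted p = 0.0419) and KLK3 by 1.22 ± 0.23 (adjusted p = 0.0224), or 2.34-fold. The 3 probe sets of KLK3 gave 1.22, 1.05 and 0.86, whereas the 4 of KLK2 gave 1.76, 0.52, -0.22 and 0.54. The list as a whole had a median of -0.05 and a mean of 0.06 (5 higher and 1 lower adjusted over the list alone, adjusted p = 0.418). MMP28, a matrix metalloproteinase, rose by 1.58 ± 0.28, MYL3 by 1.22 ± 0.27, SYT4 by 1.14 ± 0.12 (adjusted p = 0.00012), ST3GAL3 by 1.04 ± 0.21, PRR16 by 0.89 ± 0.18, LOC256021 by 0.87 ± 0.14, acetyl-CoA carboxylase ACACB by 0.85 ± 0.19 and the phosphate transporter SLC34A3 by 0.85 ± 0.17. Lower genes were TLL2 (-1.46 ± 0.30), STK40 (-1.35 ± 0.25), CILK1 (-1.20 ± 0.25), TNKS1BP1 (-1.14 ± 0.25), the stress ligand MICA (-1.12 ± 0.18), KCTD11 (-1.08 ± 0.25), LOC284356 (-0.99), TRIM59 (-0.89), GLYR1 (-0.86) and ZNF284 (-0.84). Another probe set of ST3GAL3, ACACB, TRIM59 and GLYR1 changed the opposite way. KLK2 and MMP28 lay below the brightness limit with vehicle, and TLL2, STK40 and KCTD11 with the drug. FOXA1 (-0.50 ± 0.09) and ENO2 (-0.70 ± 0.12) fell, and ELOVL6 (0.55 ± 0.10), NOP16 (0.73 ± 0.16) and TFRC (0.51 ± 0.10) rose.

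Housekeeping genes had a median of 0.12 at 10 µM (1 of 15 called, adjusted p = 0.0377) and the unfolded protein response a median of 0.14, with 0 of 19 members called by limma (adjusted p = 0.0417). Neither passed with an estimated correlation (adjusted p = 0.295 with an estimated correlation for both) or after centring (adjusted p = 0.16 and 0.143). No other list passed. A total of 104 genes were called, 39 higher and 65 lower, and 368 without the arrays of high ACTB ratio, with all 104 shared. Higher genes were 37.5% of the calls and 100% of 4 after centring. Leaving out vehicle replicate 1, 2 or 3 gave 1, 22 and 33 genes, and leaving out enzalutamide 10 µM replicate 1, 2 or 3 gave 1, 21 and 57. The authors' deposited table marks 262 probe sets.

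The effects of both doses alone shared 77 called genes, all in the same direction, where independent lists would share 3.9 in the same direction and 3.3 in the opposite. The covariance of the changes was 0.049, against 0.02 from shared arrays, and part of the excess may come from these. Between the doses alone, 3 genes were called: PYCR3 (2.65 ± 0.42) and NRGN (2.08 ± 0.31) were higher at 10 µM and the splicing kinase CLK1 was lower (-0.80 ± 0.13), each with an adjusted p of 0.0224. With 1 µM PYCR3 and NRGN lay below the brightness limit, so the sizes of these differences are uncertain. No list passed (lowest adjusted p = 0.39). Without the arrays of high ACTB ratio limma called 0 genes, with 789 at an unadjusted p under 0.05. Leaving out enzalutamide 1 µM replicate 1, 2 or 3 gave 11, 1 and 421 genes, and replicate 1, 2 or 3 of 10 µM gave 0, 7 and 1. The authors' deposited table marks 0 probe sets between these doses.

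DHT with 1 µM enzalutamide was compared with DHT alone to see which DHT effects the antagonist changed. SGK1 fell by 3.14 ± 0.35 (adjusted p = 1.61e-05), STEAP4 fell by 2.67 ± 0.58 (adjusted p = 0.0118) and the cytokine receptor LIFR fell by 2.40 ± 0.17 (adjusted p = 1.01e-07). The GTPase RHOU (-2.25 ± 0.14), the condensin subunit NCAPD3 (-2.20 ± 0.19), FKBP5 (-2.08 ± 0.16), the transcription factor MAF (-2.03 ± 0.15), OTULINL (-1.94), ERRFI1 (-1.63) and CYP2U1 (-1.60) also fell. SPTLC3, AMIGO2 and LRRN1, which DHT had lowered, were higher by 2.04 ± 0.24, 1.73 ± 0.18 and 1.61 ± 0.11, as were VWF, the von Willebrand factor (1.96 ± 0.54), ASMTL-AS1 (1.87), JAKMIP1 (1.52), the prolyl hydroxylase EGLN3 (1.5 ± 0.29), BARD1, a partner of BRCA1 (1.39 ± 0.10), C16orf89 (1.28) and VSTM2L (1.28). KLK3 (0.13 ± 0.23, adjusted p = 0.83) and KLK2 (-0.83 ± 0.39, adjusted p = 0.304) were not called, and the other probe sets of KLK2 gave -0.57, -1.17 and 0.17. ASMTL-AS1 was not called without the arrays of high ACTB ratio. SPTLC3, VWF, ASMTL-AS1, JAKMIP1, EGLN3, C16orf89 and VSTM2L lay below the brightness limit with DHT.

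Of 28 androgen-induced genes 22 fell with 1 µM beside DHT (24 adjusted over the list alone, median -0.83, adjusted p = 5.65e-37), and 5 of 11 androgen-repressed genes rose (8 adjusted over the list alone, median 0.56, adjusted p = 2.81e-08), such as ACKR3 (0.82 ± 0.11) and CAMK2N1 (0.77 ± 0.13). Glucocorticoid response genes fell in 5 of 10 cases (1 higher and 5 lower adjusted over the list alone, median -0.38, adjusted p = 3.21e-07). Cholesterol synthesis genes were lower as a list (median -0.21, adjusted p = 0.00212), with 1 of 23 called lower and 8 lower adjusted over the list alone. These lists also passed with an estimated correlation, the highest being cholesterol synthesis (adjusted p = 0.0117 with an estimated correlation). Ribosome biogenesis (median 0.17, adjusted p = 0.0153), mitosis (-0.14, adjusted p = 0.0313), polyamine (-0.08, adjusted p = 0.0313), glycolysis (0.17, adjusted p = 0.0373), ATF4 (0.21, adjusted p = 0.041) and p53 genes (0.22, adjusted p = 0.0445) passed, but not with an estimated correlation (adjusted p = 0.0844, 0.323, 0.173, 0.407, 0.407 and 0.131 with an estimated correlation). In these lists SMS (-0.81 ± 0.10), ODC1 (-0.53 ± 0.09) and VLDLR (-0.67 ± 0.15) fell and FAS (0.95 ± 0.17) and PSAT1 (0.46 ± 0.10) rose, and no ribosome, mitosis or glycolysis gene was called by limma. CCNE2 rose by 1.00 ± 0.12, and DNAJB9 (-0.78 ± 0.10) and ERN1 (-0.79 ± 0.17) fell, in lists that did not pass.

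A total of 446 genes differed between DHT with 1 µM and DHT, 156 higher and 290 lower, and 520 without the arrays of high ACTB ratio, of which 362 were shared. Higher genes were 35.0% of the calls and 45.8% of 236 after centring. The count was 269 and 282 without replicate 2 or 3 of DHT with 1 µM. The authors' deposited table marks 718 probe sets for this pair.

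With 10 µM enzalutamide beside DHT, STEAP4 fell by 5.04 ± 0.58 (adjusted p = 9.72e-06), to a level of 6.27 that lay below the brightness limit, as did that of SGK1 (6.75), and FKBP5 fell by 3.57 ± 0.16 (adjusted p = 8.56e-11). SGK1 (-3.85 ± 0.35), RHOU (-2.95 ± 0.14), OTULINL (-2.73 ± 0.23), MAF (-2.63 ± 0.15), NCAPD3 (-2.63 ± 0.19), LIFR (-2.45 ± 0.17), HPGD (-2.40 ± 0.22) and TMPRSS2 (-2.33 ± 0.25, adjusted p = 2.98e-06) also fell. SPTLC3 (2.70 ± 0.24), LRRC31 (2.15 ± 0.45), LRRN1 (2.06 ± 0.11), AMIGO2 (2.06 ± 0.18), MID1 (2.04 ± 0.41) and STXBP5L (1.67 ± 0.13), all lowered by DHT, were higher than with DHT alone. So were ANKRD20A11P (2.04 ± 0.50), VWF (1.80 ± 0.54), EGLN3 (1.67 ± 0.29) and LOC441385 (1.89 ± 0.55), the last not without the arrays of high ACTB ratio. Of these, SPTLC3, LRRC31, MID1, ANKRD20A11P, VWF, EGLN3 and LOC441385 lay below the limit with DHT, so the sizes of their changes are uncertain. KLK3 again was not called (-0.22 ± 0.23, adjusted p = 0.616), and its other probe sets gave -0.67 and -0.04, whereas KLK2 fell by 2.11 ± 0.39 (adjusted p = 0.00155). Under DHT 184 probe sets were brighter than that of KLK3.

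With 10 µM beside DHT, 25 of 28 androgen-induced genes fell (25 adjusted over the list alone, median -1.44, adjusted p = 3.9e-46), all but KLK3, CAMKK2 (0.11 ± 0.20) and IGF1R (0.20 ± 0.23). Androgen-repressed genes rose in 7 of 11 cases (9 adjusted over the list alone, median 0.60, adjusted p = 2.91e-08), with SI at 1.03 ± 0.18 and CAMK2N1 at 1.02 ± 0.13. Cholesterol synthesis genes fell in 11 of 23 cases (1 higher and 14 lower adjusted over the list alone, median -0.37, adjusted p = 1.03e-08), with INSIG1 at -0.82 ± 0.13, FDFT1 at -0.61 ± 0.12 and MSMO1 at -0.51 ± 0.12. Glucocorticoid response genes fell in 5 of 10 cases (5 adjusted over the list alone, median -0.54, adjusted p = 8.17e-08) and polyamine genes in 4 of 9 (5 adjusted over the list alone, median -0.34, adjusted p = 0.000139), with SMS at -1.24 ± 0.10 and ODC1 at -0.88 ± 0.09. All of these passed with an estimated correlation too, the polyamine list least (adjusted p = 0.0236 with an estimated correlation). The unfolded protein response had 7 of 19 lower (7 adjusted over the list alone, median -0.20, adjusted p = 2e-05), with DNAJB9 at -1.20 ± 0.10 and ERN1 at -0.88 ± 0.17. Fatty acid synthesis had ELOVL7 (-1.52 ± 0.12) and ACSL3 (-1.17 ± 0.10) lower and ACACB higher out of 17 (1 higher and 5 lower adjusted over the list alone, median -0.17, adjusted p = 0.000854). Mitosis had CDK1 (-0.55 ± 0.15) and BIRC5 (-0.37 ± 0.11) lower out of 24 (1 higher and 6 lower adjusted over the list alone, median -0.29, adjusted p = 0.000854). These last lists did not pass with an estimated correlation (adjusted p = 0.0782, 0.0851 and 0.152 with an estimated correlation). CCNE2 rose by 1.35 ± 0.12 (adjusted p = 3.74e-07), FN1 by 0.97 ± 0.13 and FAS by 1.01 ± 0.17, and KRT8 (-0.98 ± 0.27) and KRT18 (-0.87 ± 0.11) fell, in lists that did not pass.

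In all 1074 genes differed between DHT with 10 µM and DHT, 503 higher and 571 lower, and 1121 without the arrays of high ACTB ratio, of which 854 were shared. Higher genes were 46.8% of the calls and 31.1% of 573 after centring. The count was 695 and 673 without replicate 2 or 3 of DHT with 10 µM. The authors' deposited table marks 1530 probe sets. Of the genes called for DHT, 840 were also called here, 839 in the opposite direction: 469 that DHT raised were lower and 370 that it lowered were higher. Independent lists would give 86.4 opposite calls, and the covariance was -0.1125 against -0.0201 from shared arrays. For 1 µM, 379 of 380 shared genes were opposite (245 and 134), against 35.6 for independent lists, with a covariance of -0.0768 against -0.0202. Part of each excess may come from the shared arrays.

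The share of the DHT response kept beside the drug, over the 2056 genes called for DHT, was 51.6% ± 6.8 at 1 µM and 30.1% ± 2.7 at 10 µM (jackknife error), a difference of -21.4 ± 5.0 points. With genes and DHT effects taken from separate arrays the shares were 56.9% and 33.7%. Leaving out single arrays gave 43.9% to 54.0% and 26.6% to 31.0%, the lowest of each without DHT replicate 1. Genes raised and lowered by DHT kept similar shares, 52.4% and 50.5% at 1 µM and 30.8% and 29.3% at 10 µM. Single genes differed widely. At 10 µM KLK3 kept 64.2%, TMPRSS2 53.9%, KLK2 53.3%, STEAP4 21.8%, FKBP5 13.5% and SGK1 -8.8%. For SGK1 the DHT effect beside 10 µM was -0.29 ± 0.35, which cannot be told from 0. For STEAP4 the DHT effect beside 10 µM was 1.07 ± 0.59. Its levels with vehicle (6.43), 10 µM alone (5.21) and DHT with 10 µM (6.27) all lay below the brightness limit of 6.98. The shares that STEAP4 kept are therefore uncertain. At 1 µM KLK3 kept 89.7%, TMPRSS2 84.9%, KLK2 77.8%, STEAP4 63.9%, FKBP5 47.7% and SGK1 4.5%. Because the drug alone is subtracted, the rises of KLK3 and KLK2 with 10 µM alone lower their shares at that dose.

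**Figure D4:**
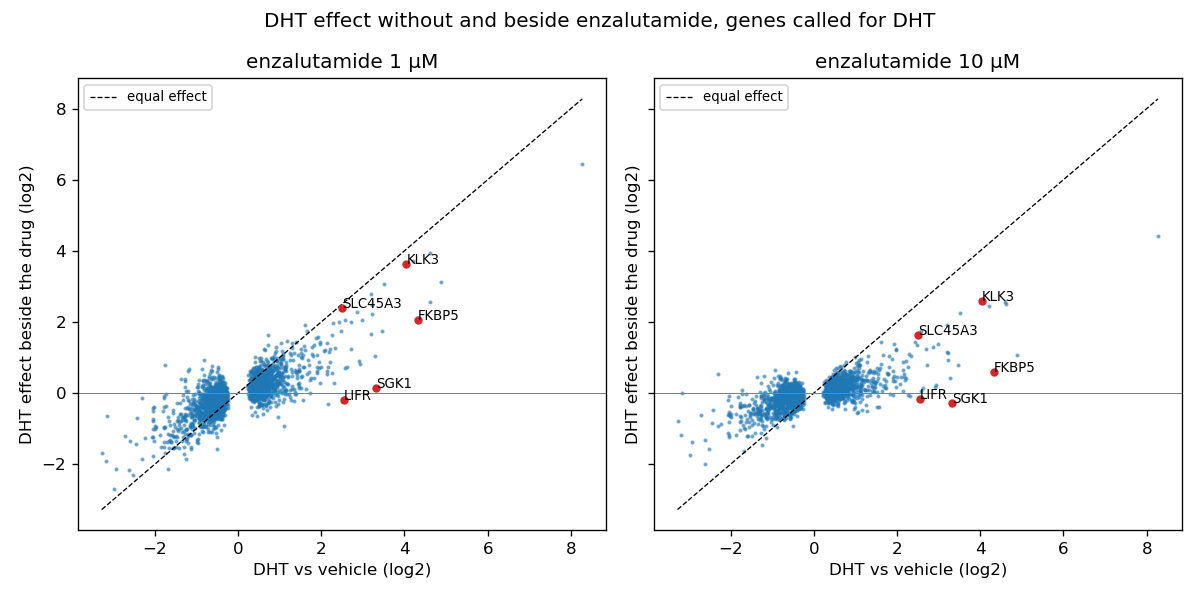
For the 2056 genes called for DHT, the DHT effect beside 1 µM (left) or 10 µM (right) enzalutamide (vertical axes, log2) is plotted against the effect of DHT without the drug (horizontal axes, log2), with the dashed line for equal effects. KLK3 lies near the line at 1 µM, where it kept 89.7% of its DHT effect, and SGK1 near 0, where it kept 4.5%.

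Interactions test whether the DHT effect differed beside the drug. At 1 µM 744 genes were called, 459 higher and 285 lower, and 472 without the arrays of high ACTB ratio, of which 350 were shared. The interaction was lower for SGK1 (-3.17 ± 0.50, adjusted p = 0.00128), LIFR (-2.74) and FKBP5 (-2.26 ± 0.23), among others, and 14 of 28 androgen-induced genes were lower (18 adjusted over the list alone, median -0.85, adjusted p = 2.96e-19), 12 without the arrays of high ratio. Higher genes were 61.7% of the calls and 77.0% of 395 after centring. Leaving out vehicle replicate 1, 2 or 3 gave 309, 387 and 448 genes, DHT replicate 2 or 3 481 and 483, enzalutamide 1 µM replicate 2 or 3 375 and 1774, and replicate 1, 2 or 3 of DHT with 1 µM 493, 360 and 326. At 10 µM 638 genes were called, 319 higher and 319 lower, and 852 without the arrays of high ratio, of which 591 were shared. FKBP5 stood at -3.74 ± 0.23 (adjusted p = 2.43e-08), KLK2 at -3.87 ± 0.55, STEAP4 at -3.81 ± 0.83 and SPTLC3 at 3.17, the last 3 with a group below the brightness limit, and the other probe sets of KLK2 gave -1.91, -2.28 and -0.60. KLK3 stood at -1.45 ± 0.33 (adjusted p = 0.0129), and 23 of 28 androgen-induced genes were lower (26 adjusted over the list alone, median -1.47, adjusted p = 3.61e-43). Most of the KLK3 value came from its rise of 1.22 with 10 µM alone, against a change of -0.22 beside DHT. Higher genes were 50% of the calls and 29.2% of 243 after centring, and vehicle replicate 1, or replicate 2 or 3 of DHT with 10 µM, left out gave 400, 393 and 421.

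Between the doses beside DHT 9 genes were called, and FKBP5 (-1.49 ± 0.16, adjusted p = 0.00031), TNFAIP8 (-0.91 ± 0.14), CENPN (-0.83 ± 0.15), PMEPA1 (-0.82 ± 0.15), ABCC4 (-0.70 ± 0.12), the NF-κB regulator MALT1 (-0.58 ± 0.09), CREB3L4 (-0.56 ± 0.07) and PLPP1 (-0.53 ± 0.09) were lower at 10 µM, while GNG7 (1.03 ± 0.18) was higher. Another probe set of PMEPA1 changed the opposite way. Androgen-induced genes were lower as a list, with 5 of 28 called (1 higher and 21 lower adjusted over the list alone, median -0.50, adjusted p = 1.71e-29). So were cholesterol synthesis (0 called by limma, 5 lower adjusted over the list alone, median -0.17, adjusted p = 3.26e-08), fatty acid synthesis (median -0.23, adjusted p = 2.59e-07), housekeeping (-0.22, adjusted p = 4.67e-07), unfolded protein response (-0.16, adjusted p = 1.82e-06), polyamine (-0.27, adjusted p = 4.51e-05), luminal (-0.16, adjusted p = 6.19e-05), glucocorticoid (-0.19, adjusted p = 8.88e-05), ribosome (-0.12, adjusted p = 0.000275) and DNA replication genes (-0.12, adjusted p = 0.0328), all of which passed with an estimated correlation. Glycolysis (-0.21, adjusted p = 4.51e-05) and mitosis (-0.08, adjusted p = 0.0411) passed, but not with an estimated correlation (adjusted p = 0.0885 and 0.338 with an estimated correlation). The median log2 signal of the arrays was 7.08 with 10 µM and 6.95 with 1 µM, so that centring adds -0.13 to each of these changes. Housekeeping genes, at -0.22, moved further than every other list named here except androgen-induced, fatty acid synthesis and polyamine genes. The smaller list shifts therefore cannot be told from a shift that housekeeping genes share. Over all genes tested the median change was 0.014. Of 9 genes 11.1% were higher, and 0% of 9 after centring. With the arrays of high ACTB ratio left out 31 genes were called, including all 9. Without replicate 1, 2 or 3 of DHT with 1 µM the count was 1, 5 and 3, and without those of DHT with 10 µM 16, 2 and 2. The authors' deposited table marks 0 probe sets here.

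DHT with enzalutamide was also compared with vehicle, which shows all differences from vehicle, including any that DHT alone did not make. With 1 µM, KLK2 (7.44 ± 0.39), KLK3 (4.18 ± 0.23), TMPRSS2 (3.55 ± 0.25), F5 (3.30 ± 0.37), NNMT (3.18 ± 0.41), PMEPA1 (2.76 ± 0.15), MGC13170 (2.57 ± 0.17), TRGC2 (2.45 ± 0.21) and LOC285463 (2.43 ± 0.67) were among the highest, and MAN1A1 (-2.48 ± 0.18), CD200 (-2.19 ± 0.34), MID1 (-2.17 ± 0.41), SI (-2.03 ± 0.18), the ion channel KCNU1 (-1.86 ± 0.42), LRRC31 (-1.81 ± 0.45), FGF13 (-1.66 ± 0.15), TAGAP (-1.65 ± 0.39), STXBP5L (-1.62 ± 0.13) and BMF (-1.54 ± 0.39) were lower. KLK2, F5, NNMT, TRGC2 and LOC285463 lay below the brightness limit with vehicle, and CD200, MID1, KCNU1, LRRC31, TAGAP and BMF with DHT and 1 µM. Androgen-induced genes were higher in 23 of 28 cases (24 adjusted over the list alone, median 1.07, adjusted p = 1.51e-35), cholesterol synthesis in 13 of 23 (17, median 0.47, adjusted p = 2.93e-15), fatty acid synthesis in 10 of 17 (10, median 0.48, adjusted p = 1.34e-09) and ribosome biogenesis in 8 of 16 (13, median 0.42, adjusted p = 5.88e-09), with NOP16 at 1.13 ± 0.16. Androgen-repressed genes were lower in 6 of 11 cases (9 adjusted over the list alone, median -0.52, adjusted p = 2.87e-07). DNA replication had 5 of 21 higher, among them MCM4 (0.76 ± 0.11) and CDC6 (0.97 ± 0.25), and CCNE2 lower (adjusted p = 0.000768). These passed with an estimated correlation, but the unfolded protein response (6 of 19 higher, adjusted p = 0.00054), glycolysis (3 of 17, adjusted p = 0.000774), polyamine (4 of 9, adjusted p = 0.00237), housekeeping (3 of 15, adjusted p = 0.0061), glucocorticoid (4 higher and 1 lower of 10, adjusted p = 0.0273) and fibroblast genes (COL1A1 lower of 5, adjusted p = 0.0293) did not (adjusted p = 0.109, 0.171, 0.0589, 0.242, 0.109 and 0.106 with an estimated correlation). In all 1284 genes were called, 699 higher and 585 lower, and 2012 without the arrays of high ACTB ratio, with all 1284 shared. Higher genes were 54.4% of the calls and 83.7% of 1125 after centring, which adds 0.16 to each change. The count was 800 and 815 without vehicle replicate 2 or 3 and 734 without replicate 1 of DHT with 1 µM. The authors' deposited table marks 2230 probe sets.

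With 10 µM beside DHT, KLK2 stood 6.17 ± 0.39 above vehicle, KLK3 3.82 ± 0.23, F5 2.60 ± 0.37, NNMT 2.55 ± 0.41, TMPRSS2 2.30 ± 0.25, MGC13170 2.03 ± 0.17, PMEPA1 1.94 ± 0.15, the transporter gene SLC45A3 1.62 ± 0.11 and GREB1 1.44 ± 0.17. DEFB124 (-1.85 ± 0.39), MAN1A1 (-1.76 ± 0.18), CD200 (-1.64 ± 0.34), SI (-1.58 ± 0.18), FLJ36779 (-1.47 ± 0.39), FGF13 (-1.18 ± 0.15), BASP1 (-1.16 ± 0.24), the glucagon gene GCG (-1.14 ± 0.22), LOC401052 (-1.13 ± 0.25) and MYLK (-1.11 ± 0.12), of which another probe set changed the opposite way, were lower. KLK2, F5 and NNMT lay below the brightness limit with vehicle, and CD200, FLJ36779, BASP1 and LOC401052 with DHT and 10 µM. FKBP5 was still 0.75 ± 0.16 above vehicle (adjusted p = 0.0118), while its DHT effect beside 10 µM, measured against the drug alone, was 0.58 ± 0.16 (adjusted p = 0.0581). Androgen-induced genes were higher in 12 of 28 cases (18 adjusted over the list alone, median 0.60, adjusted p = 1.71e-24), androgen-repressed genes lower in 3 of 11 (7 adjusted over the list alone, median -0.43, adjusted p = 1.32e-07), and cholesterol synthesis genes higher in 8 of 23 (9 adjusted over the list alone, median 0.26, adjusted p = 5.89e-11), with SQLE at 0.67 ± 0.09 and INSIG1 at 0.64 ± 0.13. Fatty acid synthesis genes were higher in 3 of 17 cases (8 adjusted over the list alone, median 0.24, adjusted p = 1.48e-05) and ribosome biogenesis genes, NOP16 and UTP20, in 2 of 16 (3 adjusted over the list alone, median 0.29, adjusted p = 6.59e-06). These lists passed with an estimated correlation, and no other list passed. In all 403 genes were called, 200 higher and 203 lower, and 769 without the arrays of high ACTB ratio, with all 403 shared. Higher genes were 49.6% of the calls and 64.7% of 167 after centring. Leaving out vehicle replicate 1, 2 or 3 gave 238, 201 and 238, and replicate 2 or 3 of DHT with 10 µM 219 and 213. The authors' deposited table marks 1388 probe sets. Of the genes called for DHT, 327 were also called here, all in the same direction, against 32.5 in the same direction for independent lists (covariance 0.0732 against 0.02), and part of the excess may come from those arrays.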

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

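The tests of RNA quality, of RNA carried over from DHT-treated cells, of agonism against different vehicle arrays, of saturation and of KLK3's own share, and the counts without the arrays of high ACTB ratio, were chosen after the results they bear on had been seen.

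The effect of DHT differed beside 1 µM enzalutamide for 744 genes by limma's interaction test. The DHT effect was shifted upwards for KLF16 (3.51, adjusted p = 0.0179), TBRG4 (3.23, adjusted p = 0.0363), KIF1A (3.12, adjusted p = 0.00924), KCNIP3 (2.93, adjusted p = 0.048), PYCR3 (2.83, adjusted p = 0.0103), VWF (2.73, adjusted p = 0.0408), SPTLC3 (2.52, adjusted p = 0.000256), the nucleoporin NUP210 (2.21, adjusted p = 0.0377), the splicing helicase DHX38 (2.11, adjusted p = 0.0266) and UNC119 (2.05, adjusted p = 0.044). It was shifted downwards for SGK1 (-3.17, adjusted p = 0.00128), LIFR (-2.74, adjusted p = 4.54e-06), FBLN1 (-2.48, adjusted p = 0.048), FKBP5 (-2.26, adjusted p = 2.02e-05), RHOU (-2.23, adjusted p = 3.92e-06), NCAPD3 (-2.11, adjusted p = 0.000217), F5 (-2.05, adjusted p = 0.03), PRR16 (-2.03, adjusted p = 0.000166), LOC284017 (-2.03, adjusted p = 0.0214) and OTULINL (-1.99, adjusted p = 0.00182). KLF16, DHX38, FBLN1, F5 and LOC284017 were no longer called without the arrays of high ACTB ratio, which left 472 genes. At least 1 group of KLF16, TBRG4, KCNIP3, PYCR3, VWF, SPTLC3, DHX38, UNC119, FBLN1, F5 and LOC284017 lay below the brightness limit, so the sizes of their shifts are uncertain. An interaction also holds the effect of the drug alone. With 1 µM alone KLF16, KIF1A, PYCR3, DHX38 and UNC119 fell, and FBLN1, PRR16 and LOC284017 rose. The shifts of these genes come in part from that change and need not mean a changed response to DHT. By camera the interaction passed for the androgen-induced (median -0.85, adjusted p = 2.96e-19), androgen-repressed (0.46, adjusted p = 0.0186), cholesterol synthesis (-0.21, adjusted p = 0.00547), glucocorticoid (-0.46, adjusted p = 0.00236) and polyamine lists (-0.34, adjusted p = 0.0215). The androgen-repressed and polyamine lists did not pass with an estimated correlation (adjusted p = 0.0868 and 0.171 with an estimated correlation).

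Beside 10 µM the DHT effect differed for 638 genes. Upward shifts were found for SPTLC3 (3.17, adjusted p = 8.75e-06), LRRC31 (2.48, adjusted p = 0.0296), STXBP5L (2.10, adjusted p = 1.2e-06), MAN1A1 (2, adjusted p = 7.11e-05), EGLN3 (1.96, adjusted p = 0.00821), the transcription factor RFX3 (1.87, adjusted p = 0.0239), MEX3B (1.81, adjusted p = 0.0418), RNFT2 (1.80, adjusted p = 4.03e-05), CCNE2 (1.71, adjusted p = 5.65e-06) and CCDC33 (1.67, adjusted p = 0.0458), the last not called without the arrays of high ACTB ratio. Downward shifts were found for KLK2 (-3.87, adjusted p = 0.000248), STEAP4 (-3.81, adjusted p = 0.00999), FKBP5 (-3.74, adjusted p = 2.43e-08), SGK1 (-3.61, adjusted p = 0.000186), RHOU (-2.87, adjusted p = 6.1e-08), OTULINL (-2.73, adjusted p = 3.24e-05), LIFR (-2.71, adjusted p = 1.52e-06), NCAPD3 (-2.70, adjusted p = 5.71e-06), HPGD (-2.66, adjusted p = 3.15e-05) and TNFAIP8 (-2.51, adjusted p = 6.89e-07), of which another probe set shifted the opposite way. At least 1 group of SPTLC3, LRRC31, MAN1A1, EGLN3, RFX3, MEX3B, KLK2, STEAP4, SGK1 and HPGD lay below the brightness limit, so the sizes of their shifts are uncertain, and the other probe sets of KLK2 gave -1.91, -2.28 and -0.60. The rise of KLK2 with 10 µM alone enters its shift as well.

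Gene lists shifted beside 10 µM as well, given here as medians with the p-values of camera, which does not test the median itself. The androgen-induced (-1.47, adjusted p = 3.61e-43), androgen-repressed (0.38, adjusted p = 0.000131), cholesterol synthesis (-0.36, adjusted p = 5.2e-09), glucocorticoid (-0.79, adjusted p = 1.37e-06), polyamine (-0.44, adjusted p = 8.38e-06) and unfolded protein response lists (-0.35, adjusted p = 1.37e-06) passed, also with an estimated correlation (highest adjusted p = 0.0418 with an estimated correlation, for the last). Fatty acid synthesis (-0.19, adjusted p = 0.000308), fibroblast markers (0.39, adjusted p = 0.0236), housekeeping (-0.24, adjusted p = 0.00303), luminal markers (-0.05, adjusted p = 0.0257) and mitosis (-0.26, adjusted p = 0.00307) passed only with the preset correlation (adjusted p = 0.0612, 0.0825, 0.19, 0.0841 and 0.181 with an estimated correlation). Luminal markers had a mean of -0.33. By their medians, housekeeping genes moved further down than fatty acid synthesis genes and nearly as far as mitosis genes. Smaller downward list shifts therefore cannot be told from a shift that housekeeping genes share, and larger ones may hold part of it. Over all genes tested the median interaction was 0.038.

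The ratio of 3′ to 5′ control signal exceeded the vehicle mean plus 3 SD on several treated arrays. For ACTB, with a limit of 1.63, it was 4.50 on DHT replicate 2, 6.04 and 1.80 on enzalutamide 1 µM replicates 2 and 1, and 1.70 on enzalutamide 10 µM replicate 2. For GAPDH, with a limit of 0.897, it was 1.21 on DHT replicate 2 and 1.12 on enzalutamide 1 µM replicate 2. The deviations of those replicates 2 from the other arrays of their groups correlated with r = 0.418 across genes, the highest of the 45 pairs of arrays with the same number.

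More genes were called for 1 µM enzalutamide alone (872) than for 10 µM alone (104). Poor RNA on replicate 2 of 1 µM is a candidate explanation. The changes of the called genes correlated with the deviation of DHT replicate 2 from its group with r = 0.493. They correlated as highly, at 0.51, with that of enzalutamide 10 µM replicate 2, whose ACTB ratio was 1.70. The difference between these 2 correlations lay within its error of 0.036, a spread worked out after the correlation was known. Correlations with the deviations of DHT replicate 1 (-0.681) and enzalutamide 10 µM replicate 3 (-0.472) were negative. Deviations within a group sum to 0, so negative values there follow from the positive ones and add no evidence of their own. Without the arrays of high ratio the counts were 425 and 368, but the gap closed partly because the 10 µM count rose. Leaving out vehicle replicate 1, not an array of high ratio, lowered the counts further, to 123 and 1. With the compared groups only the counts were 30 and 195, the reverse order, and the authors' deposited table marks 203 and 262 probe sets. A larger effect of the lower dose was tested by the mean product of independent replicate differences over all genes, which was higher at 1 µM by 0.0219 ± 0.0281 and so settled nothing. Both explanations stay open.

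KLK3 and KLK2 were among 3 androgen-induced genes higher with 10 µM enzalutamide alone. RNA of DHT-treated cells in these arrays is argued against: the rise of KLK3 would need a share of 8.6%, which predicts a median rise of 0.89 for the 13 other genes that DHT raised at least 8-fold, and their median was 0.04 ± 0.20, with all 13 below their prediction and 0 called by limma. KLK3 transcript bound by the KLK2 probe set stays open, since the test of it, a rise of KLK2 of at least 5.4% of that of KLK3, sets signals of different probe sets against each other and starts from a KLK2 level below the brightness limit, and so decides nothing. Weak agonism on DHT-responsive genes as a whole stays open too, with a slope of -0.07 ± 0.054 over 2410 genes (-0.086 ± 0.057 without these 3) on a DHT effect from which 1 µM alone is subtracted, which can pull it down, and of 0.091 ± 0.040 over all genes with different vehicle arrays for each effect, but 0.087 ± 0.069 without the arrays of high ACTB ratio. As a description, the other 25 androgen-induced genes had a median of -0.06 ± 0.06, where a rise by the share of its DHT effect seen for KLK3, 30.3%, would give 0.65.

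KLK3 was hardly lower with 10 µM enzalutamide beside DHT (-0.22 ± 0.23) while FKBP5 fell. Saturation of bright probe sets in general is argued against, because the 12 genes raised by DHT that lay above KLK3 or within 1 log2 unit below it had a median change of -1.02 ± 0.09, and -1 ± 0.09 without FKBP5, below the -0.5 set as a limit, and the 2 brighter than KLK3, DEGS1 (-0.77) and PLPP1 (-0.98), were lower too. Saturation of KLK3's own probe set was not tested. That the drug lowers the DHT effect on KLK3 less than on most genes is a hypothesis that stays open: KLK3 kept a larger share than 93.2% of the 44 genes raised at least 4-fold, but it was picked for this pattern. Its probe sets gave -0.22, -0.67 and -0.04, so the size of the fall is itself uncertain. With DHT against vehicle they gave 4.05, 4.86 and 1.58, so the share that KLK3 kept is uncertain too.

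Other groupings of the arrays were counted for each comparison. For comparisons of 3 arrays with 3 there are 10 splits, too few for a share under 0.05. Every other split mixes both groups, so a real effect enters its error, and its low count decides nothing. Fitted on these arrays alone, the real split was the 1 split with the most calls in each of the following, with the highest other after it: DHT against vehicle 1674 and 0, enzalutamide 1 µM 30 and 0, enzalutamide 10 µM 195 and 0, DHT with 1 µM against DHT 284 and 1, DHT with 10 µM against DHT 714 and 0, DHT with 1 µM against vehicle 2196 and 1, DHT with 10 µM against vehicle 1098 and 1, and the doses beside DHT 27 and 1. Between the doses alone all 10 splits called 0 genes with limma. For the interactions 100 regroupings of 12 arrays were drawn, the real included. At 1 µM the real grouping called 316 genes and the highest other 192 (1 of 100 reached it), and at 10 µM 674 and 888 (2 of 100). These regroupings mix the DHT effect into the error and so decide nothing. They were therefore drawn anew, a step chosen after the first counts were known, with the mean effects of DHT and the drug taken off each gene. At 1 µM the real grouping again called 316 genes and the highest other 1, so 1 of 100 reached it. At 10 µM the real grouping called 674 and the highest other 1297, a regrouping that set the same 6 arrays against the other 6 as the interaction does, so 2 of 100 reached it. A real interaction adds to the error of the other regroupings and so lowers their counts. These counts therefore cannot exclude chance for either interaction.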

How the results depend on the processing

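The fits without the arrays of high ACTB ratio, with that ratio as a covariate and with log2 of the signal plus 16 were chosen after the data had been seen. Settings were run on 192 gene results chosen by size of change and on 168 list results, and none of these reversed. Other list members named in the text, and the lists for DHT with enzalutamide against vehicle and between the doses alone, were not run under them. Over all settings 3044 values of these genes kept their call and 556 lost it, and list values stayed on their side of the threshold in 2925 cases, passed newly in 99 and no longer passed in 60. All 20 genes chosen for DHT against vehicle were called under every setting that tested them, but of those for enzalutamide alone only 3 of 20 at 1 µM and 1 of 20 at 10 µM. The stricter filter left out the dimmer of these genes.

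Counts that moved by over 1.5 times are given by setting, and the cause was not tested except where stated. Testing all probe sets, which tests more features, gave 3461 for DHT, 694 and 1718 for DHT with 1 and 10 µM against DHT, 1962 for DHT with 1 µM against vehicle, and 8 and 4 between the doses without and with DHT. Centring gave 329 and 4 for enzalutamide 1 and 10 µM, 236 and 573 for DHT with 1 and 10 µM against DHT, 167 for DHT with 10 µM against vehicle, 5 between the doses alone, and 395 and 243 for the interactions at 1 and 10 µM. Array weights gave 3490 and 716 for enzalutamide alone, 1874 for DHT with 10 µM against DHT, 2678 and 2238 for DHT with 1 and 10 µM against vehicle, 2126 and 744 between the doses without and with DHT, and 2221 and 1417 for the interactions, with a weight of 5.17 for enzalutamide 1 µM replicate 1 and 0.25 for its replicate 2. Without the arrays of high ACTB ratio the counts were 425 and 368 for enzalutamide alone, 2012 and 769 for DHT with 1 and 10 µM against vehicle, 0 and 31 between the doses without and with DHT, and 472 for the interaction at 1 µM. With the ratio as covariate they were 564 and 395, 1985 and 741, 0 and 34, and 359. With the compared groups only, which leaves fewer arrays to estimate the spread, they were 30 and 195 for enzalutamide alone, 284 and 714 against DHT, 2196 and 1098 against vehicle, 0 and 27 between the doses, and 316 for the interaction at 1 µM. eBayes without a trend gave 41 for enzalutamide 10 µM and 1 and 3 between the doses. No filter gave 49 for enzalutamide 10 µM and a kept share of 26.7% at 10 µM. The stricter filter gave 1 between the doses alone, and quantile normalization 5 between the doses with DHT. For each 0 limma was the tool.

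Leaving out each array in turn gave 1511 to 2036 genes for DHT, 123 to 1780 for enzalutamide 1 µM, 1 to 57 for 10 µM, 269 to 421 for DHT with 1 µM and 673 to 1009 for DHT with 10 µM against DHT, 734 to 1008 and 201 to 295 for these against vehicle, 0 to 421 and 1 to 16 between the doses without and with DHT, 309 to 1774 and 393 to 778 for the interactions, and kept shares of 43.9% to 54.0% and 26.6% to 31.0%. The array behind the 1780 and the 421 was enzalutamide 1 µM replicate 3, and behind the 1774 as well.

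Arrays share replicate numbers across groups, but the numbers did not pair them: of 45 pairs with the same number 8 had deviations correlating above 0.1 (from -0.188 to 0.418, median 0.025, against -0.004 for differently numbered pairs), and 6 of 18 arrays correlated best with their own number. With a replicate block the counts were 2162 for DHT, 1035 and 91 for enzalutamide, 478 and 1158 against DHT, 1339 and 425 against vehicle, 3 and 7 between the doses, and 935 and 667 for the interactions, with kept shares of 50.9% and 29.9%. The block ended the calls of ACACB, TNKS1BP1 and KCTD11 (10 µM alone), VWF (both doses beside DHT), PMEPA1 and PLPP1 (between the doses) and of p53 genes with 1 µM beside DHT (adjusted p = 0.0581), and immediate early genes passed between the doses with DHT (adjusted p = 0.0478).

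Other pseudocounts do not apply to values already on a log2 scale, and the second deposited table holds identical values. Log2 of the signal plus 16 moved no count by over 1.5 times. Probe sets with a mean log2 under 6.98 were not tested, so nothing is said of weakly expressed genes.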

Other observations

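The tests of agonism at 1 µM and of the glucocorticoid list were chosen after results had been seen.

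Among the 44 genes that DHT raised at least 4-fold, the median share of the DHT effect kept was 55.7% (quartiles 31.8% and 77.2%) beside 1 µM enzalutamide and 29.8% (13.3% and 49.4%) beside 10 µM. The genes at either end, chosen after their values were seen, were GLMP (67.2%), SLC45A3 (65.7%), KLK3 (64.2%) and PMEPA1 (63.9%) with the most kept at 10 µM, and SGK1 (-8.8%), LIFR (-6.4%), PRR16 (-3.0%) and the elongation factor EAF2 (-2.1%) with the least. For the last group the DHT effect beside 10 µM was at or just below 0.

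Some genes were called both for DHT and for enzalutamide alone. Of the genes called for DHT, 260 were also called for 1 µM enzalutamide alone, 196 in the same and 64 in the opposite direction, where independent lists would give 71.1 and 69.5. For 10 µM alone 47 were shared, 42 in the same and 5 in the opposite direction, where independent lists would give 8.5 and 8.3. The covariances were 0.0338 and 0.0266 against 0.0199 and 0.0201 from shared arrays, and part of the excess may come from those arrays, which cannot be split. The DHT and 1 µM groups also each hold an array of high ACTB ratio, and the deviations of these arrays correlated with r = 0.418. That correlation may add genes shared in the same direction at 1 µM, and the overlap was not counted without these arrays. With TFRC and NOP16 rising and ENO2 falling in all of these comparisons, the shared genes included members of several lists, chosen here after their values were seen.

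Weak agonism of 1 µM enzalutamide on DHT-responsive genes as a whole was tested by the slope of its effect alone on the DHT effect beside 10 µM, over 359 genes. The slope was -0.18 ± 0.024, and -0.169 without enzalutamide 1 µM replicate 2. The 10 µM arrays without DHT are subtracted in that DHT effect, so a drug effect shared by both doses and absent beside DHT could also give a slope below 0, and this test decides nothing. Over all genes, with different vehicle arrays for each effect, the slope on the DHT effect was 0.139 ± 0.111, and 0.067 ± 0.1 without the arrays of high ACTB ratio, so agonism stays open.

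A hypothesis that 10 µM enzalutamide changes genes without any need for DHT was tested over the 104 genes called for it alone. The slope of its effect beside DHT on its effect alone was -0.017 ± 0.064. Of these genes 58 changed in the same direction beside DHT, 10 were called the same way and 8 the opposite way. The genes were selected for a large effect alone, which lowers the slope, so the question stays open.

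SGK1 and FKBP5, glucocorticoid response genes, kept little of the DHT effect, and other raised members of that list might do the same. The other 2 members raised at least 2-fold, ZBTB16 (33.1%) and ERRFI1 (9.3%), kept a mean of 21.2% at 10 µM, against 26.9% for all 179 genes raised at least 2-fold (permutation p = 0.762, 100000 permutations). With 2 members the test settles nothing.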
